A study of Mus musculus with 12 samples.

How the data were processed

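The series holds 12 RNA-seq libraries of mouse limb muscle fibro-adipogenic progenitors (FAPs), in 4 groups of 3. Per the labels, cells were sorted as Lin- Vcam- Sca1+, grown in alpha-MEM with fetal bovine serum, and treated with 4-hydroxytamoxifen (4-OHT) for deletion of Bap1 or with ethanol as control. The groups are WT (ethanol), Bap1KO (4-OHT), Smn1OE (4-OHT and a human SMN vector) and Smn1OE_K186R (4-OHT and a vector for the K186R form of SMN). No group carried an empty vector, so the effect of SMN cannot be separated from that of a vector, and no group carried SMN without 4-OHT. No group received 4-OHT without deletion of Bap1, so Bap1KO against WT also compares 4-OHT with ethanol. The treatment text names a Rosa-CreER driver, whereas the source label names a Prrx1Cre conditional knockout; the groups here follow the treatment and genotype labels.

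The deposited files give raw read counts per Ensembl gene ID, 1 file per library, made by the authors before deposition with no further normalization. Their processing notes name CASAVA 1.8.2, cutadapt 1.4.2, STAR 2.6.1, HTSeq 0.9.1 and DESeq2 (no version), with GRCm39 as genome build, for paired-end TruSeq libraries sequenced on an Illumina instrument. The annotation release, the settings and the strand setting are not stated, so counts of overlapping or antisense genes are uncertain. Each file has 55335 gene rows and 5 closing rows that name no gene (no feature, ambiguous, low quality, not aligned, not unique), which were left out of library sizes and tests. Gene IDs were given symbols from GENCODE M21, an annotation of the earlier mouse build, which matched 55154 IDs, and its chromosomes X and Y were used to leave out sex-linked genes. No positions were used. Reads outside genes took 2.51, 2.64, 3.19 and 3.38% of the records in WT, Bap1KO, Smn1OE and Smn1OE_K186R, ambiguous reads 2.11, 2.1, 2.03 and 1.95%, and reads aligned to several places 5.39, 5.47, 5.5 and 5.42% (means, n = 3). All closing rows together took 11.6, 11.8, 14.2 and 13.7%.

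Total counts per library averaged 67.7 ± 0.451 M in WT, 64.1 ± 5.65 M in Bap1KO, 60.3 ± 7.87 M in Smn1OE and 61 ± 7.78 M in Smn1OE_K186R (SD, n = 3). Replicates of a group differed more than counting alone would give, with a chi-square per degree of freedom of 40.7 to 133 between library pairs, so the spread between replicates and not the depth limits the precision of abundant genes.

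Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr with a minimum count of 10 (16597 genes tested), and a quasi-likelihood fit of the 4 groups over all 12 libraries with 8 residual degrees of freedom. The common biological coefficient of variation was 0.179. Log2 fold changes carry a prior count of 0.125, and genes with a Benjamini-Hochberg adjusted p under 0.05 in 2-sided tests are called. Gene values are TMM-normalised CPM as mean ± SD over 3 libraries. Ratios to groups with no reads are given against a floor of 3 counts per library. An exact permutation test of 3 against 3 cannot give a p below 0.1, so no per-gene permutation p is reported. The 6 comparisons are Bap1KO with WT, each SMN group with Bap1KO and with WT, and Smn1OE_K186R with Smn1OE.

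The labels give 6 culture media batches: 3 hold a WT and a Bap1KO library each, and 3 hold a library of each SMN group. Pairing was checked from the data: deviations from the group means correlated across genes at 0.31, 0.43 and 0.24 within the WT and Bap1KO batches and at 0.38, 0.30 and 0.43 within the others. Pairs of different batches gave -0.35 to 0.049 between WT and Bap1KO and -0.31 to -0.041 between the SMN groups. Between an SMN library and a WT or Bap1KO library, which share no batch, the value reached 0.3. No design formula is stated, so the tests were run without a block, and a fit with the media batch as a block was the alternative for the 2 comparisons within batches. The main tests thus leave this pairing out, and in these 2 comparisons they called fewer genes than the blocked fit. For comparisons across batches, limma 3.58.1 (voom) was run with the media batch as a random effect (correlation 0.45).

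Before the data were examined, 26 gene lists (582 symbols, 580 found in the annotation) and the rule for named genes were fixed. The lists were granzymes, FAP and fibroblast identity, fibrillar collagen and matrix, contractile and TGF-beta response, adipogenic, osteochondrogenic, secreted neurotrophic and synaptogenic, cell cycle, p53 targets, inflammatory cytokines, interferon response, complement, ER stress, cholesterol biosynthesis, glycolysis and hypoxia, immediate early, SMN complex and Sm proteins, BAP1 complex, and Hox clusters. Markers of other cells were myogenic, macrophage, T and NK, endothelial, pericyte, tenocyte and Schwann lists. Lists of at least 3 tested genes were tested with limma camera at a preset correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation and with fry. No list called with the preset correlation kept its call with an estimated one.

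Named genes are Bap1, Smn1 and the measured granzymes; up to 10 largest rises and 10 largest falls per comparison among called genes with a mean log2 CPM of at least 1, no overlap of the groups' libraries, and a symbol that is not a predicted gene; up to 4 members with the smallest adjusted p per list described, and members against a list; and up to 10 genes per direction called in Bap1KO against WT that differed the opposite way in Smn1OE_K186R without a call against WT. From these the text takes a part. Results for 3 genes are not reported here. Chance alone parts the libraries of 2 groups of 3 without overlap for 10% of genes.

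The other choices fixed beforehand were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no low-count filter, a fit of only the groups compared, the replicate blocks, the random effect, fry, and leaving out each library. Fits without genes of chromosomes X and Y, blocked fits without a media batch, and list tests without Smn1 and Bap1 were added after the data were seen. Overlaps and correlations of comparisons that share libraries were set beside 20 simulated sets of unchanged groups. In simulated counts with 200 changed genes among 16186 tested, edgeR called 30 of 67 genes changed 1.5-fold, 59 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 8 false calls (4.91%), and DESeq2 made 45 false calls (20.2%) among 16597 genes tested. The simulated libraries held no batch effect. With no gene changed, edgeR made 0 calls between groups placed as Smn1OE_K186R and Smn1OE. Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining tests and the plots.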

Results

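Each of the 4 groups held 3 libraries of cultured mouse fibro-adipogenic progenitors (FAPs), the mesenchymal cells that lie between muscle fibres. WT cultures had received ethanol, and Bap1KO cultures had received 4-hydroxytamoxifen (4-OHT) to delete Bap1, a nuclear deubiquitinase that acts on histones. Smn1OE and Smn1OE_K186R cultures had received 4-OHT and a vector for human SMN, the protein that assembles spliceosomal snRNPs, in its unmutated form or in the K186R form. Library totals lay between 51.2 and 68.2 M counts, and 30896 genes had at least 1 read in some library. Replicates are separate samples per the labels, which do not say whether they came from separate animals, so each p-value measures the spread between these samples, and intervals and floors cover counting error only.

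The libraries fell apart first into those with an SMN vector and those without, a division that batches and sex-linked expression share. The first principal component carried 59% of the variance and the second 8.77%. On the first component WT replicates 1 to 3 lay at -81.4, -58.1 and -75.3 and the SMN libraries at 41.3 to 76.9. Bap1KO replicate 2 lay nearer to the SMN libraries there (-14.6) than Bap1KO replicate 1 (-60.5) or replicate 3 (-38.7). Xist, the RNA that coats the inactive X chromosome of female cells, averaged 228 ± 32.6 CPM in WT and 252 ± 54 CPM in Bap1KO (SD, n = 3). It averaged 0.0163 ± 0.0023 CPM in Smn1OE and 0.0425 ± 0.0615 CPM in Smn1OE_K186R. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had counts in the SMN groups alone, with Eif2s3y at 59.8 CPM in Smn1OE and 63 CPM in Smn1OE_K186R. Per the labels, WT and Bap1KO shared 3 culture media batches and the SMN groups shared another 3, so every comparison of an SMN group with Bap1KO or WT also compared libraries of different batches and of different sex-linked expression. Mitochondrial genes took 1.39 ± 0.095% of the counts in WT, 1.6 ± 0.0764% in Bap1KO, 1.96 ± 0.0751% in Smn1OE and 2.04 ± 0.105% in Smn1OE_K186R (SD, n = 3).

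Bap1 transcripts were lower in Bap1KO than in WT, but most of the signal remained. Bap1 averaged 50.5 ± 1.32 CPM in WT and 40.3 ± 1.74 CPM in Bap1KO, a log2 fold change of -0.32 (adjusted p = 0.0139). Counts over whole genes include transcripts that lack a deleted exon, and the labels do not say which part of the gene was removed. The call was lost without Bap1KO replicate 2, Bap1KO replicate 3 or WT replicate 3, with an adjusted p of up to 0.0689. Bap1 stood at 49.1 ± 1.4 CPM in Smn1OE, higher than in Bap1KO by 0.28 (adjusted p = 0.00924), and at 45.3 ± 3.15 CPM in Smn1OE_K186R, with a log2 fold change of 0.17 to Bap1KO (adjusted p = 0.081, or 0.0262 without Smn1OE_K186R replicate 2). Against WT, Bap1 differed by -0.04 in Smn1OE (adjusted p = 0.638) and by -0.16 in Smn1OE_K186R (adjusted p = 0.0767). Counts at Smn1 averaged 33.6 ± 1.71 CPM in WT and 32.9 ± 2.31 CPM in Bap1KO (-0.03, adjusted p = 0.915). They rose 145-fold in Smn1OE, to 4757 ± 907 CPM (adjusted p = 1.73e-10), and 120-fold in Smn1OE_K186R, to 3940 ± 363 CPM (adjusted p = 2.39e-10). The labels name human constructs, and counts at the mouse gene do not tell mouse transcripts from reads of the human sequence that align there. Smn1 differed by -0.27 between the SMN groups (adjusted p = 0.997), and neither Bap1 nor a granzyme gene was called between them.

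Among granzyme genes, which encode secreted serine proteases, Gzmc and Gzmd were lower in both SMN groups than in WT, and the read assignment is uncertain because Gzmc, Gzmd and Gzme are close copies of each other. Gzme, the gene the series title names, averaged 89 ± 4.7 CPM in WT, 61.1 ± 8.21 CPM in Bap1KO, 34 ± 20.3 CPM in Smn1OE and 43.7 ± 29 CPM in Smn1OE_K186R (SD, n = 3). Its log2 fold change was -0.54 in Bap1KO against WT (adjusted p = 0.538). Blocked on the media batch it was -0.55 with an adjusted p of 0.00656, and the alternatives for this value ran from 0.00656 to 0.699. The WT libraries (83.7 to 92.6 CPM) lay above all Bap1KO libraries (52.8 to 69.2 CPM). The main fit estimates the spread of each gene from all 4 groups, and Gzme varied more in the SMN groups. Between Smn1OE and Bap1KO Gzme differed by -0.84 (adjusted p = 0.218, alternatives 0.0273 to 0.496) and between Smn1OE_K186R and Bap1KO by -0.48 (adjusted p = 0.485). Gzme was lower in Smn1OE than in WT by -1.39 (adjusted p = 0.0388), a call lost without Smn1OE replicate 3 or any WT replicate, with an adjusted p of up to 0.088. In Smn1OE_K186R against WT it differed by -1.02 (adjusted p = 0.111, or 0.0238 without Smn1OE_K186R replicate 1). The mean of Gzme in both SMN groups thus lay below that in Bap1KO, not between Bap1KO and WT, but neither difference from Bap1KO was called in the main fit. Replicate 3 was lowest in both, at 10.5 CPM in Smn1OE and 16.5 CPM in Smn1OE_K186R. Smn1OE replicates 1 and 2 stood at 44.8 and 46.6 CPM, below every Bap1KO library. Smn1OE_K186R replicate 1, at 74.1 CPM, lay above every Bap1KO library, and replicate 2, at 40.6 CPM, below.

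Gzmc fell from 4.21 ± 1.53 CPM in Bap1KO to 0.452 ± 0.289 CPM in Smn1OE, a log2 fold change of -3.19 (adjusted p = 0.00219), and to 0.828 ± 0.456 CPM in Smn1OE_K186R, by -2.33 (adjusted p = 0.00844). Gzmd fell by -1.79 in Smn1OE (adjusted p = 0.0285) and by -1.55 in Smn1OE_K186R (adjusted p = 0.0492). The first Gzmd call was lost without Bap1KO replicate 1 or 3 or Smn1OE replicate 1 or 3 (up to 0.0958), and the other was lost without any library of the pair of groups other than Bap1KO replicate 2 (up to 0.14). Gzmm was higher in Smn1OE than in Bap1KO by 1.00 (adjusted p = 0.0335), also lost without Bap1KO replicate 1 or 3 or Smn1OE replicate 1 or 3 (up to 0.124). It differed by 0.89 in Smn1OE_K186R (adjusted p = 0.0548, or 0.023 without Bap1KO replicate 2). None of the 4 measured granzymes passed the test in Bap1KO against WT, where Gzmc differed by -0.26 (adjusted p = 0.796), Gzmd by -0.53 (adjusted p = 0.573) and Gzmm by -0.37 (adjusted p = 0.518). Blocked on the media batch, Gzmd was called there (-0.56, adjusted p = 0.0176).

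**Figure D1:**
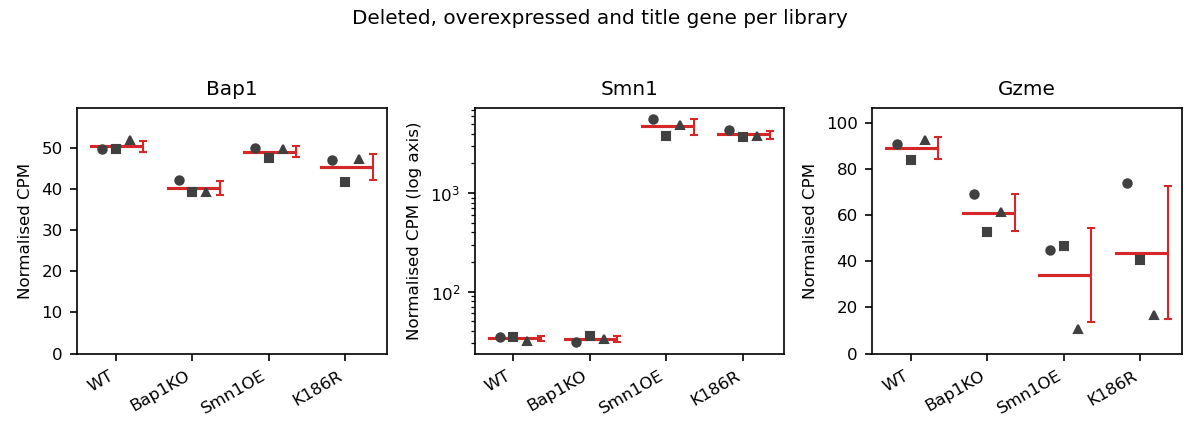
Normalised CPM of Bap1, Smn1 (log axis) and Gzme in the 4 groups, with 1 point per library (marker shape for the replicate number), a line at the mean and a bar for the SD. Bap1 has means of 50.5 CPM in WT and 40.3 CPM in Bap1KO, Smn1 rises to 4757 CPM in Smn1OE and 3940 CPM in Smn1OE_K186R, and Gzme has its highest mean in WT at 89 CPM.

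Bap1KO libraries differed from WT in genes of several kinds, and more genes fell than rose. No group received 4-OHT with Bap1 intact, so the drug and the deletion cannot be separated. Nptx1, a secreted neuronal pentraxin, rose from 1.95 ± 0.946 CPM in WT to 26.7 ± 15 CPM in Bap1KO, a log2 fold change of 3.77 (adjusted p = 0.000899). Spock2, a secreted proteoglycan, rose by 1.88 (adjusted p = 0.000899) and Plxna4, a semaphorin co-receptor, by 1.70 (adjusted p = 0.00396). Tmem176a fell from 64.3 ± 5.39 to 10.6 ± 0.877 CPM, by -2.60 (adjusted p = 0.00216), and Tmem176b from 89.7 ± 3.09 to 15.3 ± 2.15 CPM, by -2.55 (adjusted p = 0.00217). Tmem176a and Tmem176b are neighbours in the genome, and without a stated strand setting their counts are not independent. Ogn, a small leucine-rich matrix proteoglycan, fell by -2.15 (adjusted p = 0.00734), and Rtn2, a reticulon of the endoplasmic reticulum, by -1.96 (adjusted p = 0.000899). Rises of 1.68 to 2.28 were also called for Tchh, Hist1h3b, Rragd, Prrg4, the serotonin receptor gene Htr2b and the keratin gene Krt7 (adjusted p 0.00519 to 0.0487). Falls of -2.15 to -2.03 were called for Cda, Cend1, Nipsnap1, Fabp7 and Apobec3, which restricts retroviruses (adjusted p 0.00103 to 0.0181). Hist1h3b shares reads with near-identical histone genes and is uncertain.

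In all, 1614 of the 16597 genes tested passed in Bap1KO against WT, 557 higher and 1057 lower, and 547 of them differed at least 2-fold. With the media batch as a block 4814 genes passed, 1967 higher and 2847 lower, of which 1611 were among the 1614. Without Bap1KO replicate 3 the count fell to 535, without Bap1KO replicate 2 to 977, and without WT replicates 1, 2 and 3 to 671, 819 and 896. Of the 18 genes named above for this comparison, Hist1h3b, Prrg4, Htr2b, Krt7 and Apobec3 lost their call without Bap1KO replicate 2, Bap1KO replicate 3 or WT replicate 1, with an adjusted p of up to 0.147. Hist1h3b, Htr2b and Krt7 also lost it without WT replicate 2 or 3, and Krt7 without Bap1KO replicate 1.

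**Figure D2:**
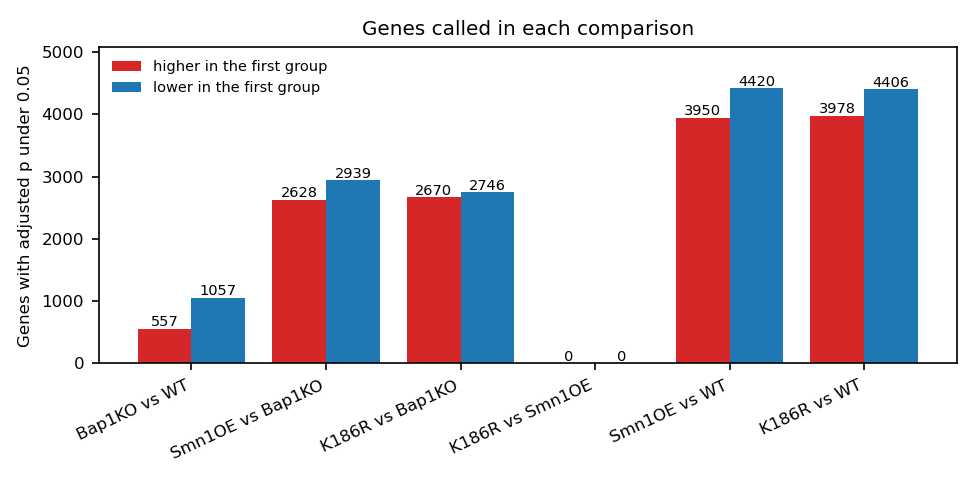
Number of genes with an adjusted p under 0.05 in each of the 6 comparisons in the fit without a block, with paired bars for genes higher (red) and lower (blue) in the first group named. Bap1KO against WT has 557 higher and 1057 lower, and Smn1OE_K186R against Smn1OE has 0 of each. With the media batch as a block, not shown, these were 1967 higher and 2847 lower, and 48 higher and 0 lower.

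Among the gene lists, cholesterol biosynthesis was lower in Bap1KO than in WT. Of its 23 measured members 8 fell and none rose, or 15 adjusted over the list alone (camera adjusted p = 3.2e-08). Pmvk fell from 15.5 ± 3.2 to 8 ± 0.789 CPM (-0.96, adjusted p = 0.00407), Mvd by -0.74 (adjusted p = 0.00515), Fdft1 by -0.63 (adjusted p = 0.00734) and Dhcr7 by -0.77 (adjusted p = 0.00874), all enzymes of sterol synthesis. The FAP and fibroblast list was called lower as well: of 24 members 3 fell and 2 rose, or 11 changed adjusted over the list alone (adjusted p = 0.007). Pdgfra, the receptor commonly used to mark FAPs, fell from 90.9 ± 15 to 33.8 ± 6.81 CPM (-1.43, adjusted p = 0.00398) and Sema3c, a secreted semaphorin, by -1.25 (adjusted p = 0.00263). Pcolce2, an enhancer of procollagen cleavage, and Tcf7l2, a Wnt effector, went against the list and rose by 1.05 (adjusted p = 0.00103) and 0.60 (adjusted p = 0.00626). The complement list was called lower with 2 of 12 members fallen, or 5 adjusted over the list alone (adjusted p = 0.013). One of the 2 was C1qtnf1, which encodes a C1q/TNF-related secreted protein and not a complement component (-1.16, adjusted p = 0.0164). Cell cycle genes were called lower as a list (adjusted p = 7e-04) although none of the 39 passed singly, over all genes or adjusted over the list alone. In that list 38 of 39 had a negative log2 fold change, such as Cdc20 at -0.60 (adjusted p = 0.0789), Ube2c at -0.70 (adjusted p = 0.0839), Cenpa at -0.63 (adjusted p = 0.0931) and Rrm2, a subunit of ribonucleotide reductase, at -0.24 (adjusted p = 0.0941).

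With an estimated correlation between genes none of these 4 lists was called, at an adjusted p = 0.96 with an estimated correlation for each. Blocking on the media batch, 20 cholesterol genes fell (21 adjusted over the list alone, adjusted p = 7.7e-11), and 31 cell cycle genes fell and 1 rose (34 adjusted over the list alone, adjusted p = 2.1e-13), each at an adjusted p = 0.16 with an estimated correlation. Blocked, the FAP list had 15 fallen and 2 risen (18 adjusted over the list alone, adjusted p = 9.7e-08, or 0.46 with an estimated correlation) and the complement list 7 fallen (8 adjusted over the list alone, adjusted p = 9.5e-06, or 0.49 with an estimated correlation). Without the block fry called none of the 4, and with it fry called all 4 lower (adjusted p = 0.001 for the cholesterol and cell cycle lists, 0.011 for the FAP and 0.017 for the complement list). Cdc20 (adjusted p = 2.65e-05), Ube2c (adjusted p = 6.05e-05), Cenpa (adjusted p = 0.000222) and Rrm2 (adjusted p = 0.00585) were then called. Without WT replicate 1 the cell cycle list was not called (adjusted p = 0.05). Without Bap1KO replicate 1 Cdc20 (adjusted p = 0.0379) and Ube2c (adjusted p = 0.0426) were called. The number of fallen cholesterol genes was 5, 4, 5 and 5 without Bap1KO replicates 2 and 3 and WT replicates 1 and 3. C1qtnf1 lost its call without WT replicate 1 or 3 (up to 0.0626).

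**Figure D3:**
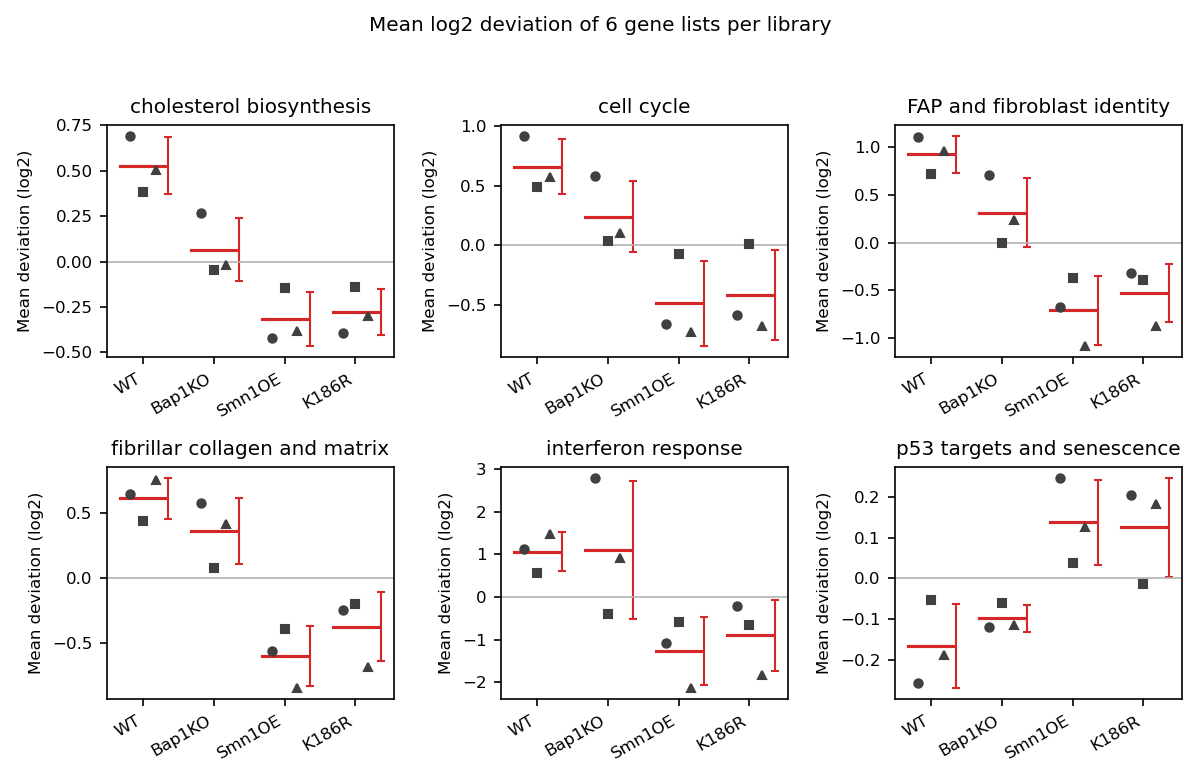
Mean log2 deviation of the measured members of 6 gene lists from each gene's mean over all 12 libraries, with 1 point per library (marker shape for the replicate number), a line at the group mean and a bar for the SD. Cholesterol genes lie lower in Bap1KO than in WT, and within Bap1KO interferon genes range from -0.40 in Bap1KO replicate 2 to 2.81 in Bap1KO replicate 1.

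Several lists were not called in Bap1KO against WT but held single changed genes. Of 26 p53 targets 6 rose and 2 fell, or 12 changed adjusted over the list alone (adjusted p = 0.12). Cdkn1a, the cell cycle inhibitor p21, rose from 652 ± 27.4 to 922 ± 50.4 CPM (0.50, adjusted p = 0.00686), Eda2r by 0.51 (adjusted p = 0.00575) and Polk by 0.45 (adjusted p = 0.0213), and Sesn1 fell by -0.77 (adjusted p = 0.0192). Of 35 secreted neurotrophic and synaptogenic genes 5 fell, the same number adjusted over the list alone, among them Wnt5a (-0.63, adjusted p = 0.00697), Slit2 (-0.96, adjusted p = 0.0352), Lama5 (-0.56, adjusted p = 0.0351) and Fst, the activin antagonist follistatin (-0.90, adjusted p = 0.0438). In the matrix list 1 of 33 fell, also 1 adjusted over the list alone: Thbs2, a thrombospondin, went from 958 ± 63.2 to 360 ± 21.8 CPM (-1.41, adjusted p = 0.0151). Ndrg1 (1.38, adjusted p = 0.00697) and Gpi1 (0.36, adjusted p = 0.0249) rose among 25 glycolysis and hypoxia genes, 2 adjusted over the list alone. The blocked fit called the matrix list lower (15 fell, 3 rose, adjusted p = 0.0025, or 0.76 with an estimated correlation), the neurotrophic list lower (17 fell, 7 rose, adjusted p = 0.0046, or 0.49) and the glycolysis list higher (8 rose, 1 fell, adjusted p = 0.042, or 0.76). Polk, Sesn1, Slit2 and Gpi1 lost their calls without Bap1KO replicate 2 or 3 or WT replicate 1 or 3, and Slit2 and Gpi1 also without WT replicate 2 (up to 0.111). Lama5 lost it without Bap1KO replicate 1 or 2 or WT replicate 2 or 3 (up to 0.117), Fst without any library of either group (0.067 or more), and Thbs2 without Bap1KO replicate 3 (0.065). Risen p53 genes numbered 3, 2, 2 and 2 without Bap1KO replicates 2 and 3 and WT replicates 1 and 3, and the list was called higher without WT replicate 2 (0.018). Fallen neurotrophic genes numbered 2 without Bap1KO replicate 2 or 3, 3 without WT replicate 1 and 1 without WT replicate 2 or 3. Single omissions also called the matrix list lower (0.036 without WT replicate 2), the contractile list lower (0.021 without Bap1KO replicate 2) and the glycolysis list higher (0.0064 without Bap1KO replicate 2, 0.038 without WT replicate 3).

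Libraries with unmutated SMN differed widely from Bap1KO libraries, in sex-linked and in other genes. Eif2s3y, Ddx3y, Kdm5d and Uty were at least 1238-fold, 601-fold, 276-fold and 238-fold higher in Smn1OE, computed against a floor of 3 counts per library. Crmp1, a neuronal cytoskeletal regulator, rose from 0.525 ± 0.272 to 4.57 ± 0.822 CPM (3.11, adjusted p = 0.000289) and Lce1g, a gene of the cornified envelope, by 3.11 (adjusted p = 0.0101). Serpinb9g (4.86, adjusted p = 0.000305) and Serpinb9e (3.19, adjusted p = 0.00168), copies in the family of the granzyme B inhibitor, and the histone gene Hist1h4d (3.29, adjusted p = 0.000395) rose too, with reads that close copies share. Col14a1, a fibril-associated collagen, fell from 19.5 ± 15 to 0.349 ± 0.177 CPM (-5.75, adjusted p = 0.00121), Abi3bp by -4.88 (adjusted p = 0.00124), Cilp by -4.53 (adjusted p = 0.00138) and Thbs4 by -4.42 (adjusted p = 0.00061). Slc1a3, a glutamate transporter, fell by -4.88 (adjusted p = 0.000227), Il1rn, the interleukin-1 receptor antagonist, by -4.59 (adjusted p = 0.00121), and Rerg, a small GTPase, by -4.31 (adjusted p = 0.00039). The interferon-induced genes Iigp1 and Oasl2 fell by -4.90 (adjusted p = 0.00791) and -4.72 (adjusted p = 0.00599). Neither was called with the media batch as a random effect, at 0.137 and 0.105, the highest of their alternatives.

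In total 5567 genes passed between Smn1OE and Bap1KO, 2628 higher and 2939 lower, and 1829 of them differed at least 2-fold. Without Bap1KO replicate 1 the count was 3512 and without Smn1OE replicate 3 it was 3524. Without genes of chromosomes X and Y, 5380 genes passed. Smn1OE and Bap1KO shared no media batch, so the vector, the batches and the sex of the cells cannot be separated.

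Matrix genes formed the most strongly called list between Smn1OE and Bap1KO: of 33 members 22 fell and 1 rose, or 24 changed adjusted over the list alone (adjusted p = 9.3e-12). Col1a1, the main fibrillar collagen chain, fell from 9441 ± 2262 to 3181 ± 844 CPM (-1.57, adjusted p = 0.000645), and Loxl1, Fbln5 and P4ha1, which act in elastic fibre and collagen assembly, fell by -0.86, -1.22 and -0.76 (adjusted p = 0.000265, 0.000283 and 0.000319). Tnc, the matrix glycoprotein tenascin-C, rose by 0.51 (adjusted p = 0.027, up to 0.0998 without Bap1KO replicate 1 or 3 or Smn1OE replicate 2 or 3). Of the 24 FAP and fibroblast genes 17 fell and 1 rose, or 20 adjusted over the list alone (adjusted p = 8.6e-06). Ly6a, which encodes the Sca1 antigen on which the cells were sorted, fell from 718 ± 133 to 276 ± 73.5 CPM (-1.38, adjusted p = 0.000995), Pi16 by -3.55 (adjusted p = 0.00145) Cxcl14 by -3.53 (adjusted p = 0.0016) and Mfap5 by -1.26 (adjusted p = 0.000703). Cd34, a sialomucin of progenitor cells, rose from 23.5 ± 4.86 to 65.3 ± 31.8 CPM (1.47, adjusted p = 0.00612). In the tenocyte list 4 of 9 fell, or 5 adjusted over the list alone (adjusted p = 0.00028), with Fmod at -3.94 (adjusted p = 0.000104), Comp at -3.68 (adjusted p = 0.000189) and Tnmd at -2.43 (adjusted p = 0.000646). Of 37 interferon response genes 34 fell, or 36 adjusted over the list alone (adjusted p = 3e-08), among them Oas1a (-4.21, adjusted p = 0.00361), Dhx58 (-2.88, adjusted p = 0.00384), Stat2 (-2.65, adjusted p = 0.00384) and Irf9 (-1.58, adjusted p = 0.00455). Each list called for this comparison had an adjusted p = 0.52 with an estimated correlation, and fry called each except the interferon list (adjusted p = 0.056). The interferon list had 17 fallen genes without Bap1KO replicate 1 and 21 without Smn1OE replicate 3, and the FAP list had 11 without Bap1KO replicate 1.

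Proliferation and metabolic lists were lower in Smn1OE too. Cell cycle genes fell for 23 of 39 members, or 31 changed adjusted over the list alone (adjusted p = 5.7e-07), such as Rrm2 (-0.60, adjusted p = 0.000645), Tyms (-0.79, adjusted p = 0.00622) and Ccne1 (-0.62, adjusted p = 0.00855). The mean log2 deviation of this list was -0.661, -0.0741 and -0.722 in Smn1OE replicates 1 to 3, and -0.587, 0.0143 and -0.675 in Smn1OE_K186R. Bap1KO replicates 1 to 3 stood at 0.583, 0.0372 and 0.104. In both SMN groups the library of media batch E (replicate 2) thus lay near Bap1KO replicates 2 and 3. Of 25 glycolysis and hypoxia genes 12 fell, or 14 adjusted over the list alone (adjusted p = 0.00031), and of 23 cholesterol genes 12 fell, or 14 adjusted over the list alone (adjusted p = 0.0014). Pfkl fell by -0.64 (adjusted p = 0.00432), Pdk1 by -1.32 (adjusted p = 0.00457), Mvk by -0.67 (adjusted p = 0.000646) and Mvd by -0.73 (adjusted p = 0.00165). The complement list had 6 of 12 fallen, or 8 adjusted over the list alone (adjusted p = 0.017), with C1ra at -2.25 (adjusted p = 0.00415). The p53 list was called higher with 9 of 26 risen and 3 fallen, or 13 changed adjusted over the list alone (adjusted p = 0.017). Pmaip1, which encodes the pro-apoptotic protein Noxa, rose from 15.7 ± 4.77 to 64.1 ± 6.74 CPM (2.03, adjusted p = 0.000129), Mdm2, the ubiquitin ligase of p53, from 239 ± 34 to 513 ± 59.5 CPM (1.10, adjusted p = 0.000227), Trp53inp1 by 0.82 (adjusted p = 0.000377) and Eda2r by 0.67 (adjusted p = 0.000425). Btg2, Sesn1 and Ephx1 fell against that list, by -0.97, -0.76 and -0.50 (adjusted p = 0.00167, 0.00726 and 0.00727).

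The list of SMN complex and Sm proteins was called higher (adjusted p = 0.016) with 4 of 24 risen and 1 fallen, or 5 adjusted over the list alone, but its median log2 fold change was -0.0072 and its mean 0.3. The call rested on Smn1: without it the adjusted p was 0.71, the median -0.0098 and the mean -0.0025, in a test added after the data were seen. Strap rose by 0.28 (adjusted p = 0.00647), Gemin5 by 0.29 (adjusted p = 0.0176) and Tgs1 by 0.36 (adjusted p = 0.0223), and Gemin8 fell by -0.49 (adjusted p = 0.0238). Gemin5, Tgs1 and Gemin8 lost their calls without Bap1KO replicate 1 or 3 or Smn1OE replicate 3, Tgs1 and Gemin8 also without Smn1OE replicate 1 and Tgs1 without Smn1OE replicate 2 (up to 0.0878). The list was not called without Bap1KO replicate 3 (adjusted p = 0.06), nor the p53 list without Smn1OE replicate 1 (adjusted p = 0.054). Without Bap1KO replicate 1, Smn1OE replicate 1 and Smn1OE replicate 3, the cell cycle list had 6, 7 and 6 fallen genes, the cholesterol list 5 each and the complement list 2 each. The complement list had 3 without Bap1KO replicate 3 and the glycolysis list 7 without Smn1OE replicate 3. Of 35 neurotrophic and synaptogenic genes 9 fell and 5 rose (19 adjusted over the list alone), without a camera call for the list, which fry called lower (adjusted p = 0.038). Lama5 (-1.05, adjusted p = 0.000703) and Lamb2 (-1.01, adjusted p = 0.000769), laminin chains of the synaptic basal lamina, fell, and Sema3e (2.08, adjusted p = 0.000973) and Nrg1, a ligand of ErbB receptors (1.14, adjusted p = 0.0018), rose.

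Libraries with K186R SMN differed from Bap1KO in much the same genes. Of the genes called, 4408 were called in the same direction in both SMN groups against Bap1KO, 2129 higher and 2279 lower, where independent lists of these sizes would share 909. Both comparisons share the Bap1KO libraries, and simulated groups with no change shared 0.05 genes on average and 1 at most. Prrg4, a vitamin K-dependent membrane protein, rose from 0.614 ± 0.197 to 4.8 ± 0.744 CPM (2.97, adjusted p = 0.000324). Serpinb9g (4.51, adjusted p = 0.000519), Serpinb9e (2.96, adjusted p = 0.00266) and Hist1h4d (3.16, adjusted p = 0.000602) rose, again with shared reads. Col14a1 fell from 19.5 ± 15 to 0.543 ± 0.41 CPM (-5.11, adjusted p = 0.00187), Abi3bp by -4.11 (adjusted p = 0.00246), Slc1a3 by -4.03 (adjusted p = 0.000546), Cilp by -3.79 (adjusted p = 0.00284) and Thbs4 by -3.37 (adjusted p = 0.00181). Itga11, a collagen-binding integrin, fell from 41.7 ± 26.4 to 4.2 ± 2.28 CPM (-3.30, adjusted p = 0.00244). Oasl2 (-4.12, adjusted p = 0.00984), Lum (-3.73, adjusted p = 0.0208) and Isg15 (-3.66, adjusted p = 0.0187) fell as well. Without Bap1KO replicate 1 none of those 3 was called (Oasl2 at 0.0537), Lum was also lost without Smn1OE_K186R replicate 1 or 3 (up to 0.212), and Isg15 without Smn1OE_K186R replicate 2 or 3 (up to 0.134). The Y-linked Eif2s3y, Ddx3y, Kdm5d and Uty were at least 1304-fold, 926-fold, 312-fold and 291-fold higher in Smn1OE_K186R.

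In this comparison 5416 genes passed, 2670 higher and 2746 lower, 1495 of them at least 2-fold. The count was 3385 without Bap1KO replicate 1, 3462 when only the compared groups were fitted, and 5204 without genes of chromosomes X and Y. Smn1OE_K186R and Bap1KO likewise shared no media batch and differed in sex-linked expression.

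The lists called for Smn1OE_K186R against Bap1KO were again led by matrix genes, with 21 of 33 fallen and 1 risen, or 22 adjusted over the list alone (adjusted p = 6.5e-07). Col1a1 fell to 3763 ± 631 CPM (-1.33, adjusted p = 0.00154) Loxl1 by -0.77 (adjusted p = 0.000542) and Fbln5 by -0.94 (adjusted p = 0.00114), while Tnc rose by 0.66 (adjusted p = 0.00857). Of 37 interferon response genes 30 fell, or 35 adjusted over the list alone (adjusted p = 8.4e-07), such as Dhx58 (-2.57, adjusted p = 0.00656), Ifi27 (-1.20, adjusted p = 0.00675) and Irf7 (-2.79, adjusted p = 0.00735). Of 24 FAP genes 10 fell and 1 rose, or 11 adjusted over the list alone (adjusted p = 0.00085), with Pi16 at -3.86 (adjusted p = 0.00131), Ly6a at -1.17 (adjusted p = 0.00242) and Cd34 at 1.37 (adjusted p = 0.00904). Of 9 tenocyte genes 4 fell, the same adjusted over the list alone (adjusted p = 0.001), with Fmod at -3.05 (adjusted p = 0.000367) and Comp at -3.21 (adjusted p = 0.000424). Cell cycle genes fell for 19 of 39, or 26 adjusted over the list alone (adjusted p = 1.7e-06), with Rrm2 at -0.54 (adjusted p = 0.00116) and Ube2c at -0.99 (adjusted p = 0.0094). Glycolysis (11 of 25 fell, 13 adjusted over the list alone, adjusted p = 0.00086), cholesterol (12 of 23 fell, 14 changed adjusted over the list alone, adjusted p = 0.0031) and complement genes (3 of 12 fell, 2 adjusted over the list alone, adjusted p = 0.043) were also called lower. Every list called here had an adjusted p = 0.64 with an estimated correlation, and fry did not call the interferon (0.099), cell cycle (0.072), cholesterol (0.065) and complement lists (0.078).

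The adipogenic list was called lower in Smn1OE_K186R with 8 of 22 fallen and 2 risen, or 11 adjusted over the list alone (adjusted p = 0.022). Adipoq, the adipokine adiponectin, fell from 4.24 ± 1.02 to 1.22 ± 0.595 CPM (-1.79, adjusted p = 0.00597) and Dgat2, an enzyme of triglyceride synthesis, by -0.79 (adjusted p = 0.0041). Plin2, a coat protein of lipid droplets, rose against the list from 182 ± 50.6 to 460 ± 126 CPM (1.34, adjusted p = 0.00252), and Fasn, the fatty acid synthase, by 0.27 (adjusted p = 0.0295). The p53 list was called higher with 9 of 26 risen and 2 fallen, or 14 changed adjusted over the list alone (adjusted p = 0.025). Pmaip1 rose by 1.85 (adjusted p = 0.00026), Mdm2 by 1.09 (adjusted p = 0.0003) and Trp53inp1 by 0.98 (adjusted p = 0.000222), and Btg2 and Ephx1 fell by -0.88 and -0.44 (adjusted p = 0.00304 and 0.0145). The list of BAP1 partners was called higher with 4 of 13 risen, the same adjusted over the list alone (adjusted p = 0.046), or 0.058 without Bap1 itself (0.047 with fry), a test added after the data were seen. Mbd6 (0.78, adjusted p = 0.00307), Asxl2 (0.48, adjusted p = 0.0162) and Mbd5 (0.50, adjusted p = 0.0179) rose. Of 24 SMN complex genes 4 rose and 2 fell, 6 adjusted over the list alone, without a call (adjusted p = 0.11, or 0.7 without Smn1). Of 35 neurotrophic genes 7 fell and 6 rose, 13 adjusted over the list alone, without a call. Lama5 fell by -0.96 (adjusted p = 0.00122) and Lamb2 by -0.85 (adjusted p = 0.00195), and Sema3e (1.99, adjusted p = 0.00137) and Wnt5a (0.71, adjusted p = 0.00141) rose.

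Leaving out single libraries ended several of these K186R calls. The p53 list was not called without Bap1KO replicate 3 (0.051) or Smn1OE_K186R replicates 1 (0.068) or 3 (0.067), nor the adipogenic list without Bap1KO replicate 3 (0.051) or Smn1OE_K186R replicate 2 (0.058). The complement list was not called without Bap1KO replicate 3 (0.053) or Smn1OE_K186R replicate 3 (0.17), nor the BAP1 list without Bap1KO replicate 2 (0.2) or Smn1OE_K186R replicate 2 (0.17), where Asxl2 and Mbd5 also lost their calls (up to 0.0678). Fasn was lost without Bap1KO replicate 1 or 3 or Smn1OE_K186R replicate 2 or 3 (up to 0.123), and the SMN list was called without Smn1OE_K186R replicate 2 (0.021). Fallen cell cycle genes numbered 7 and 12 without Bap1KO replicates 1 and 3, and 9, 33 and 7 without Smn1OE_K186R replicates 1, 2 and 3. Fallen interferon genes numbered 7 without Bap1KO replicate 1 and 15 and 12 without Smn1OE_K186R replicates 2 and 3. Fallen cholesterol genes numbered 4 without Bap1KO replicate 1 and 6 and 7 without Smn1OE_K186R replicates 1 and 3, and fallen glycolysis genes 7 without Bap1KO replicate 3 and 7 without Smn1OE_K186R replicate 3.

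The K186R and unmutated SMN groups shared their media batches and sex-linked expression, and 0 or 48 genes were called between them, depending on the fit. Without a block no gene passed in edgeR, with 388 genes at an unadjusted p under 0.05, and none in DESeq2 or in limma with the media batch as a random effect. With the media batch as a block 48 genes passed, all 48 higher in Smn1OE_K186R and higher in 3 of 3 batches, and 1910 had an unadjusted p under 0.05. They included the neutrophil chemokines Cxcl5 (1.18, adjusted p = 0.000158, at 43 ± 28.6 against 19.7 ± 14.2 CPM) and Cxcl1 (0.97, adjusted p = 0.00265). Matrix and tendon genes among them were Thbs2 (0.42, adjusted p = 0.0118), Thbs4 (1.06, adjusted p = 0.0229), Fmod (0.90, adjusted p = 0.0229) and Prelp (1.01, adjusted p = 0.0112), and secreted growth and guidance factors were Slit3 (0.61, adjusted p = 0.0273), Igf1 (0.40, adjusted p = 0.0298) and Fgf10 (0.46, adjusted p = 0.0304). Svep1 (0.84, adjusted p = 0.00215), Cyp1b1 (0.53, adjusted p = 0.00215) and Cemip, a hyaluronan-binding protein (0.62, adjusted p = 0.00265), were called as well. Each of these genes had an adjusted p of 0.997 without the block. Leaving out media batch D left 1 gene called in the blocked fit, leaving out batch F 15 and leaving out batch E 43.

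Small shifts of whole lists were called between the SMN groups although no member passed singly without the block, over all genes or adjusted over the list alone. Matrix genes were higher with K186R SMN (31 of 33 positive, adjusted p = 1.6e-07, or 0.71 with an estimated correlation), as were inflammatory genes (23 of 25 positive, adjusted p = 8.8e-05, or 0.71 with an estimated correlation). FAP (adjusted p = 0.004), neurotrophic (adjusted p = 0.025) and interferon genes (adjusted p = 0.019) were higher too, at 0.71, 0.71 and 0.86 with an estimated correlation. The SMN complex list was lower (adjusted p = 0.015, or 0.84 with an estimated correlation), and without Smn1 the adjusted p was 0.028. With the media batch as a block 3 matrix genes rose (18 adjusted over the list alone, list adjusted p = 2.3e-18, or 0.3 with an estimated correlation), 3 inflammatory genes (9 adjusted over the list alone, 1.2e-17, or 0.25) and 3 neurotrophic genes (11 adjusted over the list alone, 3.7e-07, or 0.25). Blocked, 2 FAP genes rose (6 adjusted over the list alone, 2.4e-06, or 0.39), the tenocyte list was called with 2 risen (4 adjusted over the list alone, 2.2e-05, or 0.34) and the complement list with none (4 adjusted over the list alone, 0.0025, or 0.6). Fry called 0 of the 26 lists between the SMN groups with the block, where camera called 8, and 0 without it. Without Smn1OE replicate 3 or Smn1OE_K186R replicate 1 the inflammatory list (0.27 and 0.73), the FAP list (0.55 and 0.29), the neurotrophic list (0.23 and 0.32), the interferon list (0.93 and 0.96) and the SMN list (0.19 and 0.12) were not called. Without Smn1OE_K186R replicate 2 the neurotrophic list (0.12), the interferon list (0.12) and the SMN list (0.69) were not called. The cell cycle list, not called with all libraries, was called higher without Smn1OE replicate 2 (6.7e-07) or Smn1OE_K186R replicates 1 (0.049) or 3 (0.035), and lower without Smn1OE_K186R replicate 2 (0.00022). The adipogenic list was called lower without Smn1OE replicate 3 (0.015) or Smn1OE_K186R replicate 1 (0.026), and the cholesterol list higher without Smn1OE replicate 2 (0.023). Without Smn1OE_K186R replicate 3 the complement (0.0059) and tenocyte lists (0.035) were called higher and the ER stress list lower (0.043).

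Against WT the SMN groups differed in about as many genes as each other. Smn1OE had 8370 genes called, 3950 higher and 4420 lower, and Smn1OE_K186R had 8384, 3978 higher and 4406 lower, in groups that shared no media batch and differed in sex-linked expression. Gzmc was lower than in WT by -3.45 in Smn1OE (adjusted p = 0.000557) and by -2.59 in Smn1OE_K186R (adjusted p = 0.00232), and Gzmd by -2.33 (adjusted p = 0.00484) and -2.08 (adjusted p = 0.00853). Gzmm differed from WT by 0.63 (adjusted p = 0.119) and 0.52 (adjusted p = 0.199). Smn1 was higher than in WT by 7.15 (adjusted p = 1.79e-10) and 6.88 (adjusted p = 2.47e-10). Matrix genes were lower than in WT for 25 of 33 members in Smn1OE and 24 in Smn1OE_K186R.

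Some genes that differed between Bap1KO and WT stood nearer to the WT level in Smn1OE_K186R. The genes named here were chosen by their values in Smn1OE_K186R, and the pattern is not particular to that group. Genes called the opposite way to the Bap1KO change and not called against WT numbered 173 in Smn1OE and 168 in Smn1OE_K186R. Usp29, named below, was also higher in Smn1OE than in Bap1KO, by 3.2 (adjusted p = 0.001). Rundc3a fell from 1.46 ± 0.269 CPM in WT to 0.267 ± 0.0337 CPM in Bap1KO (-2.44, adjusted p = 0.00186) and stood at 1.24 ± 0.122 CPM in Smn1OE_K186R, higher than in Bap1KO by 2.21 (adjusted p = 0.000933) and at -0.23 to WT (adjusted p = 0.537). Ptprb, a receptor phosphatase, fell by -2.69 in Bap1KO (adjusted p = 0.00546) and was higher in Smn1OE_K186R than in Bap1KO by 2.25 (adjusted p = 0.00422). Usp29, an imprinted gene, fell by -2.35 (adjusted p = 0.0136) and was higher by 2.89 (adjusted p = 0.00182), and Fabp7, a fatty acid-binding protein, fell by -2.03 (adjusted p = 0.00639) and was higher by 1.23 (adjusted p = 0.0213). Vgf, a secreted neuropeptide precursor, rose from 10.4 ± 3.03 to 29 ± 11.7 CPM in Bap1KO (1.48, adjusted p = 0.0147) and stood at 11.2 ± 3.95 CPM in Smn1OE_K186R, lower by -1.37 (adjusted p = 0.00776). Gli1, a Hedgehog effector, rose by 2.16 (adjusted p = 0.0222) and was lower by -1.93 (adjusted p = 0.0129), Adora2a rose by 1.63 (adjusted p = 0.00564) and was lower by -0.92 (adjusted p = 0.0227), and Plin4 rose by 1.20 (adjusted p = 0.00766) and was lower by -0.86 (adjusted p = 0.0122). Without Bap1KO replicate 3 the Bap1KO to WT calls of Usp29, Gli1 and Vgf (up to 0.0924) and the Smn1OE_K186R to Bap1KO calls of Fabp7, Gli1, Adora2a and Plin4 (up to 0.076) were lost. Against WT the other 7 genes differed in Smn1OE_K186R by -0.80 to 0.70 without a call. The rule that chose these genes required opposite calls in Bap1KO against WT and Smn1OE_K186R against Bap1KO, and no call against WT. Their lack of a call against WT is thus no result. Both calls use the same Bap1KO libraries, so chance values in those libraries push the 2 changes in opposite directions. Gli1 and Vgf also lost the first call without WT replicate 1 or 2. Adora2a lost the other call without Bap1KO replicate 2 or Smn1OE_K186R replicate 2 or 3, and Fabp7 without Smn1OE_K186R replicate 2. Adora2a differed from WT in Smn1OE_K186R without Smn1OE_K186R replicate 3 or WT replicate 1 (down to 0.0115), and Fabp7 without WT replicate 3 (0.0292).

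With all libraries in, such opposite changes over all genes were fewer than unrelated lists of the same sizes would share. Of the 1614 genes called in Bap1KO against WT, 220 were called in the opposite direction in Smn1OE against Bap1KO, 149 of them lower in Bap1KO, where independent lists would give 266 (98.6 and 167 by direction). For Smn1OE_K186R the count was 198, 141 of them lower in Bap1KO, against 262 (92.2 and 170). Another 452 and 459 genes moved further in the direction of the Bap1KO change, more than the 220 and 198 that moved the opposite way. The number that independent lists would share in that direction was not computed. Of the opposite genes 173 and 168 were not called against WT. Simulated unchanged groups that share the Bap1KO libraries gave no opposite genes and a correlation of log2 fold changes across genes of -0.501 and -0.502, where the observed values were 0.0702 and 0.0669. The covariances were 0.0421 and 0.0374, against -0.0599 in the simulations for each. The 3 Bap1KO libraries cannot be split between the comparisons. Without Bap1KO replicates 1 and 3 and WT replicates 1, 2 and 3 the Smn1OE count was 126, 72, 108, 106 and 120, and the Smn1OE_K186R count 100, 59, 100, 89 and 101. Without Bap1KO replicate 2 the counts rose to 254 and 221, although the genes called in Bap1KO against WT fell to 977. What independent lists would share was not computed for these omissions, so the shortfall is shown only with all libraries in. The opposite count was 111 for Smn1OE_K186R when only the compared groups were fitted, and DESeq2 gave 360 and 315.

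For the pair of SMN groups the log2 fold changes correlated across genes at 0.937, against 0.502 in the simulations, with a covariance of 0.81 against 0.0603. The simulations hold the shared Bap1KO libraries but no effects, and the independent lists hold no shared libraries, so the excess over either was not read as a shared effect. The comparison of Bap1KO with WT and that of Smn1OE_K186R with Smn1OE share no library, and their log2 fold changes correlated across genes at -0.0226, against 0.000197 in simulated unchanged groups (-0.0349 to 0.0466). The covariance was -0.00475 against 1.23e-05. Genes are not independent replicates, and the sign turned without Bap1KO replicate 2 (0.0588), Smn1OE replicate 3 (0.0584), Smn1OE_K186R replicate 2 (0.0718) or WT replicate 3 (0.00905).

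The remaining lists were called by camera in no comparison with all libraries in. With fry the osteochondrogenic list was called lower in both SMN groups against Bap1KO (adjusted p = 0.011 and 0.024), the T and NK list higher (0.021) and the granzyme list lower (0.044) in Smn1OE, and the Schwann list lower in Smn1OE_K186R (0.024). With the media batch as a block fry also called the osteochondrogenic and pericyte lists lower in Bap1KO against WT (0.011 each). The mean log2 deviation of the osteochondrogenic list shows no clear fall, at 0.298, 0.288 and 0.286 in Bap1KO replicates 1 to 3 and 0.124, 0.302 and 0.39 in WT. Of 10 myogenic genes 1 fell in Bap1KO against WT and 1 rose in each SMN group against Bap1KO, and of 9 macrophage genes 1 rose and 1 fell, then 3 rose and 2 fell in Smn1OE and 2 rose and 2 fell in Smn1OE_K186R. Of 4 T and NK cell genes 2 rose in Smn1OE, of 5 Schwann cell genes 1 fell in Smn1OE_K186R, and of 9 endothelial genes 2 fell in Bap1KO and 2 rose and 2 fell in each SMN group. Of 10 pericyte genes 1 fell in Bap1KO and 3 rose and 2 fell in each SMN group. The contractile and TGF-beta list (21 measured) had 1 fallen in Bap1KO and 4 risen and 5 fallen in each SMN group. The osteochondrogenic list (17) had 2 risen and 3 fallen in Bap1KO, 2 risen and 7 fallen in Smn1OE and 2 risen and 8 fallen in Smn1OE_K186R. The ER stress list (28) had 1 risen and 2 fallen, 5 risen and 10 fallen, and 3 risen and 9 fallen, and the immediate early list (23) 2 risen and 1 fallen and then 6 risen and 8 fallen in each SMN group. Of 34 Hox genes 1 fell in Bap1KO, 2 rose and 2 fell in Smn1OE and 2 rose in Smn1OE_K186R. Of 4 granzymes none changed in Bap1KO, 1 rose and 2 fell in Smn1OE and 2 fell in Smn1OE_K186R. Adjusted over the list alone, Bap1KO against WT had 4 changed myogenic, 3 macrophage, 2 endothelial, 2 pericyte, 1 contractile, 7 osteochondrogenic, 5 ER stress and 4 immediate early genes, and no T and NK, Schwann, Hox or granzyme gene. With the media batch as a block that comparison had more changed genes over all genes: 3 risen and 11 fallen contractile, 4 and 5 osteochondrogenic, 5 and 6 ER stress, 6 and 9 immediate early, 4 and 3 Hox, 2 and 2 myogenic, 4 and 2 macrophage, 1 and 2 endothelial, 1 and 5 pericyte and 1 and 1 Schwann genes, 2 fallen granzymes, and no T and NK gene. Adjusted over the list alone and without the block, the counts for Smn1OE against Bap1KO were 1, 5, 4, 5, 9, 10, 16 and 14, with 2 T and NK, 1 Hox and 3 granzyme genes and no Schwann gene.

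Lists called in some comparisons and not in others had these further counts. In Bap1KO against WT no interferon gene changed, singly or adjusted over the list alone, 1 of 25 inflammatory genes rose (none adjusted over the list alone), 1 of 22 adipogenic genes rose and 1 of 9 tenocyte genes rose, Bap1 was the 1 gene of its own list to fall, and no SMN complex gene changed. Blocked on the media batch, 4 inflammatory genes rose and 8 fell, 6 adipogenic genes rose and 5 fell, 1 tenocyte gene rose and 3 fell, 3 BAP1 partners and 3 SMN complex genes rose and 1 of each list fell, 10 p53 targets rose and 6 fell, and no interferon gene changed. The interferon list was called lower there without Bap1KO replicate 1 (0.0028) and higher without Bap1KO replicate 2 (0.00018). In Smn1OE against Bap1KO 3 adipogenic genes rose and 8 fell (11 adjusted over the list alone, with the list called lower by fry at 0.041), 3 inflammatory genes rose and 9 fell (12 adjusted over the list alone), and 3 BAP1 partners rose, Bap1 included (2 adjusted over the list alone). Without Bap1KO replicate 1 or Smn1OE replicate 1 the adipogenic list (0.021 and 0.0065) and the inflammatory list (0.032 and 0.0098) were called lower, as was the osteochondrogenic list without Bap1KO replicate 1 (0.039). Fallen ER stress genes numbered 6 without Bap1KO replicate 1 and 3 without Smn1OE replicate 1, and fallen inflammatory genes 5 without Bap1KO replicate 1 or Smn1OE replicate 3. In Smn1OE_K186R against Bap1KO 3 inflammatory genes rose and 5 fell, or 9 changed adjusted over the list alone. The adjusted p of the lists that were not called ran from 0.087 to 0.96 in Bap1KO against WT, 0.058 to 0.97 in Smn1OE against Bap1KO, 0.11 to 0.87 in Smn1OE_K186R against Bap1KO and 0.12 to 0.81 between the SMN groups. Among lists that were not called, the median, the mean and the test differed in sign in Bap1KO against WT for the inflammatory, ER stress, SMN complex, Hox, macrophage and endothelial lists. They also differed in Smn1OE against Bap1KO for the contractile, ER stress and macrophage lists, in Smn1OE_K186R against Bap1KO for the contractile and SMN complex lists, and between the SMN groups for the contractile, Hox, myogenic, macrophage and pericyte lists.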

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

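The tests in this part were chosen after the results were seen, with their thresholds set after their values were known. The fit of only the groups compared and the fits without a single library had themselves been planned. A larger share of reads was not aligned in the SMN libraries: 3.49 ± 0.225% in Smn1OE and 2.9 ± 0.127% in Smn1OE_K186R, against 1.61 ± 0.162% in WT and 1.56 ± 0.299% in Bap1KO (SD, n = 3), and each SMN library lay above the highest WT library (1.7%). The share of reads outside genes was 3.19 ± 0.303% in Smn1OE and 3.38 ± 0.424% in Smn1OE_K186R, with each SMN library above the highest WT library (2.61%).

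Reads of the human SMN construct or vector that do not align to the mouse genome are a candidate source of the unaligned reads. Over the 6 SMN libraries the share not aligned rose with the Smn1 count (Pearson r = 0.885, exact permutation p = 0.0194, adjusted 0.0388; Spearman rho = 0.943, exact permutation p = 0.0167, adjusted 0.0334), and it was higher in Smn1OE in 3 of 3 media batches. The permutation treats the 6 libraries as exchangeable and ignores that they form 3 batch pairs in 2 groups. Without the 2 libraries farthest from the median r was 0.278 over 4 libraries, although in both SMN groups the 3 shares followed the order of the Smn1 counts, and for the reads outside genes no relation passed the test (r = 0.117, exact permutation p = 0.758; rho = 0.0857, exact permutation p = 0.919). A difference between the sets of libraries other than the construct stays open as well: the lowest SMN library stood at 2.82%, and no library of that set lacks a vector. The unaligned reads themselves were not analysed here.

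Calls of 5567 and 5416 genes between the SMN groups and Bap1KO set these libraries apart from the others. In Smn1OE against Bap1KO 5377 of the 5567 called genes lie outside chromosomes X and Y. That was bound to be the bulk, since only 527 tested genes lie on X and 6 on Y, with 185 and 5 called. The count therefore tests no cause. The tables argue against ordinary variation between media batches: each of the 6 libraries of this comparison has a batch of its own, so the spread within groups holds that variation, and 5044 genes were called when only they were fitted. A systematic difference between the sets of cultures other than SMN, such as their batches, the sex of the donors or carriage of a vector, cannot be told apart from the SMN effect, because 0 media batches hold libraries with and without an SMN vector. A biological effect of SMN or of sex on these genes stays open, and neither was tested apart from the other.

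Interferon response genes were lower in the SMN groups than in Bap1KO, and Bap1KO replicate 1 stood highest of all libraries, at a mean log2 deviation of 2.81 against -0.40 and 0.92 in replicates 2 and 3. For Smn1OE 17 of 37 members were still called lower without that library (list adjusted p = 1.3e-07, or 0.54 with an estimated correlation). Not every call thus rested on Bap1KO replicate 1. The members move together, so the 17 calls are not separate evidence. Bap1KO replicate 2 (-0.40) also lay near Smn1OE replicate 2 (-0.58), so what remains leans on Bap1KO replicate 3. For Smn1OE_K186R 7 members were called lower without Bap1KO replicate 1 (list adjusted p = 6.4e-05, or 0.67 with an estimated correlation), too few to decide. In Smn1OE 27 members were also called lower than in WT. An effect of SMN or its vector and another difference between the sets of cultures would each give that. The count therefore does not tell them apart, and either may contribute.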

How the results depend on the processing

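The fits without a media batch, without chromosomes X and Y and without Smn1 and Bap1 in the lists were chosen after the data were seen, and the other alternatives were planned. The cause of each change below was not tested, except that leaving out libraries or fitting only the groups compared leaves fewer samples. For Bap1KO against WT, 1614 genes became 2560 with DESeq2, 4635 with the media batch as a random effect, 4814 with it as a block, and 3777, 3084 and 2880 in blocked fits without media batch A, B and C, which share 3457, 2964 and 2822 genes with the full blocked fit. Leaving out single libraries of the groups compared, as in all ranges here, gave 535 to 1457, and leaving out Smn1OE_K186R replicate 2 gave 2046. Without single libraries Smn1OE against Bap1KO ranged from 3512 to 5627 and Smn1OE_K186R against Bap1KO from 3385 to 5309, with 3462 from only the groups compared. Smn1OE_K186R against Smn1OE went from 0 to 48 with the block, and to 1, 43 and 15 in blocked fits without media batch D, E and F, of which 1, 30 and 14 were among the 48. Leaving out single libraries of the groups compared moved the counts against WT by less than 1.5 times (6944 to 7796 and 6823 to 7782).

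The opposite overlaps, 220 for Smn1OE and 198 for Smn1OE_K186R, became 360 and 315 with DESeq2 and 536 and 493 with the random effect. Without single libraries they ranged from 72 to 254 and from 59 to 221, and the second was 111 from only the groups compared. The correlation of -0.0226 ranged from -0.1 to 0.0718 and turned positive in 4 of 12 omissions. The lists called in Bap1KO against WT went from 4 to 7 without a filter, 7 with the block, 0 with an estimated correlation, 0 with fry, 7 with fry and the block, and 3 to 7 without single libraries. An estimated correlation left 0 of the 10 lists in Smn1OE against Bap1KO, 0 of the 11 in Smn1OE_K186R against Bap1KO and 0 of the 6 between the SMN groups, where fry also left 0 and single omissions 2 to 10. Fry kept 9 of those 10 and 7 of those 11 and called 14 and 9 lists in all. Leaving Smn1 and Bap1 out of the lists gave 4, 9, 10 and 6.

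Directions that turned without single libraries, none of them called, were those of Smn1 (-0.0807 to 0.0307) and Gzmc (-0.606 to 0.0312) in Bap1KO against WT, Gzme (-0.254 to 0.75) and Gzmd (-0.0987 to 0.75) between the SMN groups, and Gli1 (-0.0606 to 0.585) and Vgf (-0.214 to 0.37) in Smn1OE_K186R against WT. Of 234 single gene values, 190 of them called, 233 kept direction and call with DESeq2 size factors, 227 with the Wald test, 222 with the random effect, 224 without a filter and 224 with only the groups compared. No direction turned in these 5 settings. Of 1404 values without single libraries 1266 were kept, 119 lost the call, 8 gained it and 11 turned. The media batch block added 18 calls among 76 values and lost 0, and of those the report gives the ones that change a statement. Without a block, simulated counts with no batch effect gave 44.8% of 1.5-fold and 88.1% of 2-fold changes, so smaller changes were often missed in that fit.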

Other observations

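The lists in this part and the tests on them were chosen after the data were seen, as were the regroupings of the libraries. Replication-dependent histone genes were higher in Bap1KO than in WT: 12 of 47 measured rose in Bap1KO against WT and none fell (camera adjusted p = 8.4e-09, or adjusted p = 0.22 with an estimated correlation), and 21 rose with the media batch as a block. The linker histone genes Hist1h1c (0.78, adjusted p = 0.000899), Hist1h1d (1.29, adjusted p = 0.00238) and Hist1h1e (1.39, adjusted p = 0.00415) were among them, in a comparison where the cell cycle list was called lower. In Smn1OE against Bap1KO 28 rose (adjusted p = 2.4e-12, or 0.061 with an estimated correlation), and in Smn1OE_K186R 30 (adjusted p = 1.6e-12, or 0.073 with an estimated correlation), such as Hist1h1d at 1.00 (adjusted p = 0.00207) and 1.07 (adjusted p = 0.00172) and Hist1h2bg at 1.36 (adjusted p = 0.00117) and 1.41 (adjusted p = 0.00118). No histone gene changed between the SMN groups in edgeR, with or without the block. Most histone messages lack a poly(A) tail and their genes are near-identical copies, so counts of single histone genes are uncertain, and the selection of RNA for these libraries is not stated.

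Of 7 genes in the Serpinb9 family, which includes the granzyme B inhibitor Serpinb9, 2 rose in Bap1KO against WT (adjusted p = 0.031, or 0.46 with an estimated correlation) and 7 in each SMN group against Bap1KO (adjusted p = 5.6e-08 and 3e-07, or 0.061 and 0.073 with an estimated correlation). These copies share reads and are uncertain. Of 25 imprinted genes 11 rose and 5 fell in Smn1OE and 8 rose and 4 fell in Smn1OE_K186R, without a camera call for the list (adjusted p = 0.065 and 0.071), which fry called (0.022 and 0.032). Igf2r, the receptor that clears insulin-like growth factor 2, rose by 0.47 (adjusted p = 0.0031) and 0.63 (adjusted p = 0.000954). Cdkn1c, a growth-restricting cell cycle inhibitor, rose from 4.63 ± 2.42 CPM in Bap1KO to 24.6 ± 8.54 CPM in Smn1OE (2.40, adjusted p = 0.00178) and 19.1 ± 8.84 CPM in Smn1OE_K186R (2.04, adjusted p = 0.00422), and Dio3, a deiodinase, fell from 97.3 ± 43.4 to 4.97 ± 4.3 CPM in Smn1OE (-4.27, adjusted p = 0.00729). Of 8 keratins 2 rose in Bap1KO against WT and 3 in each SMN group against Bap1KO, with 2 and 1 fallen there, and Krt18 rose by 3.49 (adjusted p = 0.0021) and 3.23 (adjusted p = 0.00341). Of 3 prolactin-like Prl2c genes, also near-identical copies, 2 rose in each SMN group, and fry called the list (0.022 and 0.036). The SMN groups shared no media batch with Bap1KO and differed from it in sex-linked expression here too.

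Splits of the same 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave the most called genes in 1 of 10 splits for each of 5 comparisons: 1614 in Bap1KO against WT, 5567 and 5416 in the SMN groups against Bap1KO, and 8370 and 8384 against WT, where the highest other split gave 0 each. Between the SMN groups all 10 splits gave 0. With the block, 4 splits part all batch pairs, and the real ones gave 4814 and 48 where the highest other gave 0. Every other split holds libraries of both groups on each side, so the group difference adds to its spread. The counts of 0 in these splits are thus no support for the calls of the real ones. As many lists as the real 4 were called in 9 of 10 splits in Bap1KO against WT (highest other 9), and as many as the real 6 in 8 of 10 between the SMN groups (highest other 13). In the SMN groups against Bap1KO 3 and 3 of 10 splits called as many lists as the real 10 and 11 (highest others 12 and 11). The splits compare only the number of lists called, not which lists passed or how strongly. The other splits also hold part of the group difference. They therefore do not decide whether the list calls at the preset correlation differ from chance.

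For the opposite overlap, 50 groupings of the 9 libraries were drawn. For Smn1OE only the real grouping, 1 of 50, gave as many as 220 genes (highest other 0), but 0 of the 49 others called genes in both comparisons, so their overlap was bound to be 0 and the count does not show whether chance can be excluded. For Smn1OE_K186R 2 of 50 gave as many as 198, the other with 4314 genes, many times the real count: its middle group is the 3 Smn1OE_K186R libraries, a structure of the samples. It was the 1 of 49 others with calls in both comparisons, so this count is void as well. With all libraries in, both overlaps lie below the 266 and 262 genes that independent lists would share. For the correlation of -0.0226 across genes, 78 of 100 pairs of splits gave one as large in size (largest other 0.34), so it is not distinguishable from chance.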
